A study of Homo sapiens with 20 samples.

How the data were processed

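RNA-seq of human endometrium was measured in 20 libraries of 4 groups: whole endometrium in the proliferative (6) and mid-secretory phase (5), and epithelium in the proliferative (4) and mid-secretory phase (5). The labels' protocols give TRIzol extraction and standard Illumina libraries. How the epithelium was separated is not given in the sources used here. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.4 to human genome build hg19 and expression was estimated with Cufflinks 2.0.2. The gene annotation, the handling of reads that match several genes, and any scaling between libraries are not given in the sources used here. PGR ChIP-seq from the same work is not analysed here.

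The deposited table holds FPKM, fragments scaled by transcript length and by the mapped fragments of the library, of 28502 genes in 1 column per library, and 0 sample columns were left unused. The totals per library lie between 401926 and 477945 in whole proliferative, 511845 and 619165 in whole mid-secretory, 378988 and 508813 in epithelium proliferative and 417224 and 574565 in epithelium mid-secretory libraries. Genes listed at 0 number 8342 to 8644, 8268 to 8966, 7663 to 8153 and 8383 to 9792 in the same order. The values hold no counts, so absolute depth is unknown. Relative depth was worked out from the steps between low FPKM values of 940 genes, given relative to the median library. It is 0.914 to 1.20 in whole proliferative, 0.71 to 1.48 in whole mid-secretory, 1.20 to 1.73 in epithelium proliferative and 0.325 to 1.17 in epithelium mid-secretory libraries. Of 190 library pairs, 174 (91.6%) fit these depths within 0.05 on the log2 scale. In the deposited values 28.1% of the ratios between libraries lie at the fitted step, with a median of 35 genes per pair. On 20 simulated libraries the largest error was 0.416%. Those hold simple counts with 1 exact step per gene, so the error of the depths given here is not known. Correlations between libraries ran from 0.731 to 0.978, and 0 pairs were identical.

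XIST, TSIX and Y-linked genes (77 genes) were left out before testing. GSTM1, which a common germline deletion removes in many people, gets no values, though it counts as a member of the antioxidant list and was called lower in the proliferative tissue comparison. Genes at 1 FPKM or more in at least 4 libraries were tested, 15420 in all, on log2(FPKM + 1). A means model over the 4 groups was fitted to all 20 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, Benjamini-Hochberg over all genes tested), and a gene was called at an adjusted p below 0.05. There were 5 contrasts: mid-secretory minus proliferative in whole endometrium and in epithelium, the difference of these changes (epithelium minus whole, called phase by tissue), and epithelium minus whole in each phase. Adjusted p-values given for single genes are limma's. Overlaps were compared with the number expected from independent calls. Means of FPKM are given with the SD between libraries. No scaling between libraries was added, because none is named by the authors for these FPKM.

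There were 28 gene lists written from general knowledge: 18 pathway lists (receptivity, proliferative phase genes, cell cycle, steroid receptors and progesterone targets, WNT, retinoic acid, steroid metabolism, ion and solute transport, metallothioneins, complement and secreted defence, cytokines, interferon, TGF-beta and BMP, matrix and proteases, integrins and adhesion, decidualization, unfolded protein, antioxidant defence), 9 cell type marker lists (epithelial, ciliated, stromal, endothelial, smooth muscle, lymphocyte and natural killer, macrophage, B and plasma cell, red blood cell) and 1 handling list of immediate early and heat shock genes. Some genes are on several lists. Lists were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 28 lists of a contrast), and again with the correlation estimated from the residuals. Members were also counted after adjustment over the list alone. Members with near-identical copies, such as metallothioneins, HSPA1A and HSPA1B, XCL1 and XCL2, and the globins, depend on how shared reads were assigned.

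Groups, contrasts, lists, thresholds, the naming rule and the alternatives were chosen before the data were examined, apart from 4 alternatives added later. Genes are named by this rule: in each phase comparison the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, 5 of each in the other contrasts, up to 4 members per list by size of change, and always PGR and ESR1. Genes named outside the rule are marked as such. The alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization, a fit on own groups only, array weights, a 2-fold minimum, the replicate number as a block, the library code prefix as a covariate, the first prefix alone, and leaving out each library. Added after the data were seen were leaving out genes listed at 0 in every library of a group and at 10 FPKM or more in every library of another (3 genes), leaving out the 3 epithelium libraries with the lowest array weights, the handling list median as a covariate, and the second prefix alone for whole endometrium by phase and mid-secretory tissue. The library codes carry 2 prefixes of unknown meaning, treated as a possible batch: the first holds 4, 3, 4 and 3 libraries of the 4 groups and the second 2, 2, 0 and 2.

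The replicate numbers of the labels recur in all groups but do not say that a number marks 1 woman. Correlations of same-numbered libraries after removing group means gave no pair of groups in which all exceeded 0.1 (0 of 4 for whole mid-secretory with epithelium proliferative, and 4 of 5 for whole proliferative with epithelium mid-secretory), so the groups were treated as unpaired. The pipeline was tested on simulated data: of 100 genes changed 2-fold and 100 changed 4-fold among 15420, 75 and 97 were called in whole endometrium, 59 and 96 in epithelium, 28 and 87 for phase by tissue, 63 and 94 for proliferative tissue and 67 and 97 for mid-secretory tissue, with 9, 14, 4, 10 and 10 false calls. Of 3 lists shifted on purpose 3 were called, and 0 of the 25 others. The changed genes were drawn from those with a mean log2(FPKM + 1) above 2, and each gene had the same spread in all libraries. The rates for single genes therefore do not cover genes of low FPKM or libraries of unequal spread. The simulated genes vary independently, so the list test does not show how often lists of correlated genes are called falsely. In the real values the estimated correlation is 0.62 for the cell cycle and 0.84 for the ciliated list. Other splits of the libraries were drawn 100 at a time with a fixed seed. For phase by tissue the residuals of a fit with equal phase changes were also shuffled over all libraries and added back to its fitted values, a test added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.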

Results

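Endometrium was sampled in the proliferative phase, when estrogen drives growth, and in the mid-secretory phase, when progesterone has prepared the tissue for an embryo. RNA was sequenced from whole endometrium (6 proliferative and 5 mid-secretory libraries) and from epithelium (4 and 5). The questions put to the values are which genes and pathways change between the phases in each kind of sample, whether whole endometrium and epithelium change alike, and what sets epithelium apart from whole endometrium. The table lists 28502 genes in FPKM, of which 15420 were tested. A gene is called at a limma adjusted p below 0.05, and fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low FPKM. The labels do not say whether the libraries of a group come from separate women or whether whole and epithelium libraries share donors, so the p-values measure spread between these samples.

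The libraries separate by phase first and by kind of sample second. The first principal component carries 42.2% of the variance and places proliferative libraries at negative scores (mean -59.7 in whole endometrium and -37.0 in epithelium) and mid-secretory libraries at positive ones (37.4 and 63.9), with SDs within groups of 3.80 to 6.47. The second carries 18.9% and has positive group means for whole endometrium (17.9 and 43.0) and negative ones for epithelium (-47.5 and -26.5).

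**Figure D1:**
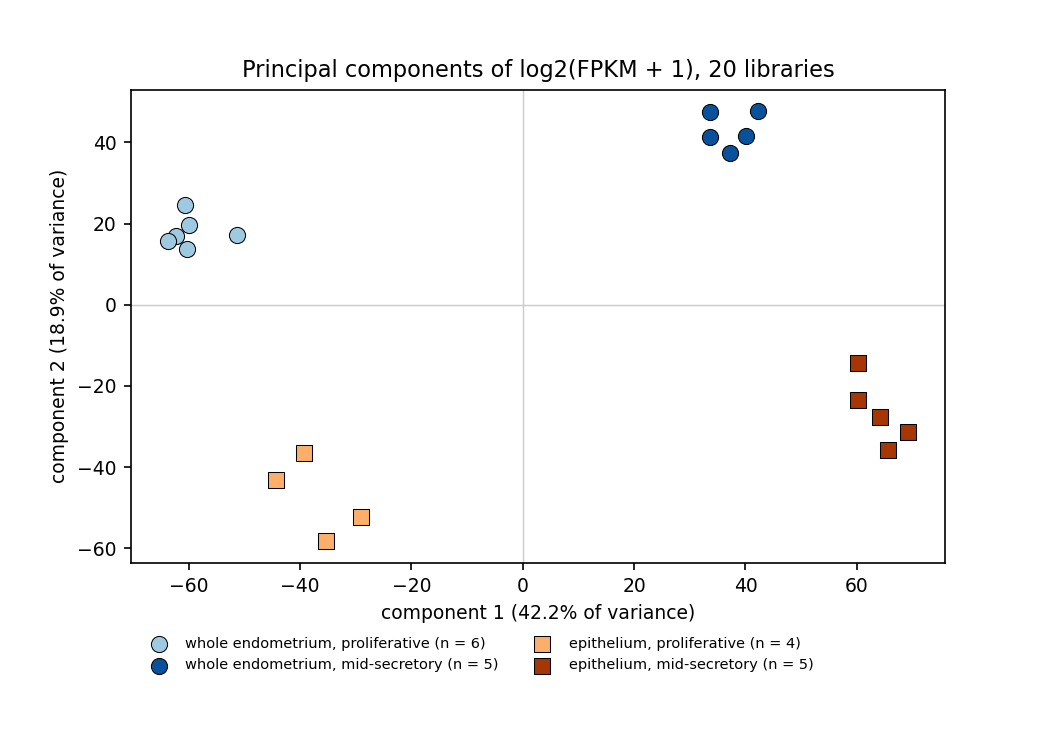
Principal component scores of the 20 libraries from log2(FPKM + 1), with the first component (42.2% of the variance) on the horizontal axis and the second (18.9%) on the vertical axis; each point is 1 library, marked by its group. Group means on the first component are -59.7 and -37.0 in the proliferative groups and 37.4 and 63.9 in the mid-secretory groups.

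In whole endometrium the mid-secretory phase brings high secreted defence and metal-binding transcripts and loses the proliferative ones. CXCL14, a chemokine that draws monocytes and natural killer cells, and GPX3, a secreted glutathione peroxidase, rise from low levels to very high ones. The WNT inhibitor DKK1 and the complement inhibitor C4BPA rise with them. SFRP4, a secreted WNT antagonist, the metalloproteinases MMP26, MMP11 and MMP7, and the hedgehog ligand IHH fall. The receptors for progesterone (PGR) and estrogen (ESR1) fall as well. The list of steroid receptors and progesterone targets, which also holds IHH, splits: 13 rose, 9 fell and 8 did not pass. HSD17B2, FKBP5 and FOXO1 are among its risers.

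Between the phases 4774 of 15420 genes are called, 2418 higher and 2356 lower in the mid-secretory phase, and 2068 of them change at least 2-fold (1133 higher, 935 lower). A fit on own groups only calls 6020 and array weights 6931, where the same settings give 3293 and 4392 in epithelium. Within the libraries of the first library code prefix alone (4 proliferative and 3 mid-secretory) 3077 are called, 1583 higher and 1494 lower. The second prefix holds 2 libraries of each phase. There 783 are called, 392 higher and 391 lower, in a fit chosen after the data were seen. CXCL14 rises from 1.34 ± 0.591 to 1042 ± 380.5 FPKM (mean ± SD, n = 6 and 5), a log2 change of 8.75 (SE 0.33, limma adjusted p = 1.59e-13). GPX3 goes from 15.7 ± 4.77 to 3229.7 ± 1404 FPKM, a change of 7.54 (SE 0.38, limma adjusted p = 1.02e-11). DKK1 goes from 0.774 ± 0.340 to 167 ± 40.2 FPKM (6.55, SE 0.31) and C4BPA from 0.690 ± 0.222 to 118 ± 28.3 FPKM (6.11, SE 0.24). C2CD4A rises by 6.92 (limma adjusted p = 2.81e-13), TCN1, which binds vitamin B12, by 6.84 (limma adjusted p = 3.32e-10), and SLC3A1, part of a cystine transporter, by 6.21 (limma adjusted p = 1.21e-08). The metallothionein MT1H rises by 6.61 (limma adjusted p = 1.32e-07). The calcium-binding S100P rises by 6.45, with a wide spread (357 ± 474 FPKM in the mid-secretory phase). GAST, the gastrin precursor, is listed at 0 in 5 of the 6 proliferative libraries and stands at 219 ± 140.1 FPKM in the mid-secretory ones. COL3A1 and PAEP are called as well, but each is listed at 0 in every library of a group, and no fold change is given for them.

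Among falling genes SFRP4 drops from 2241 ± 836 to 52.7 ± 27.1 FPKM, a log2 change of -5.45 (SE 0.31, limma adjusted p = 8.37e-11), and the organic cation exporter SLC47A1 from 79.6 ± 12.1 to 1.55 ± 0.323 FPKM, a change of -4.98 (SE 0.19, limma adjusted p = 1.47e-13). The metalloproteinases change by -5.26 (MMP26), -4.75 (MMP11) and -4.12 (MMP7), with limma adjusted p of 1.49e-04, 1.91e-07 and 4.29e-07. The hormone precursors TRH and PENK change by -4.67 and -4.22, and SPDEF, a transcription factor of secretory epithelia, by -4.43. IHH goes from 159.7 ± 78.1 to 6.65 ± 2.65 FPKM, a change of -4.29 (SE 0.38, limma adjusted p = 3.79e-08). PGR goes from 117 ± 25.9 to 21.3 ± 2.80 FPKM (-2.38, limma adjusted p = 1.88e-06) and ESR1 from 159 ± 27.7 to 47.2 ± 5.18 FPKM (-1.72, limma adjusted p = 2.15e-07). For MMP11 mid-secretory replicate 4 stands at 65.4 FPKM against 16.9 to 28.2 in the others, and for MMP26 proliferative replicate 1 at 1175 against 215 to 362 FPKM.

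**Figure D2:**
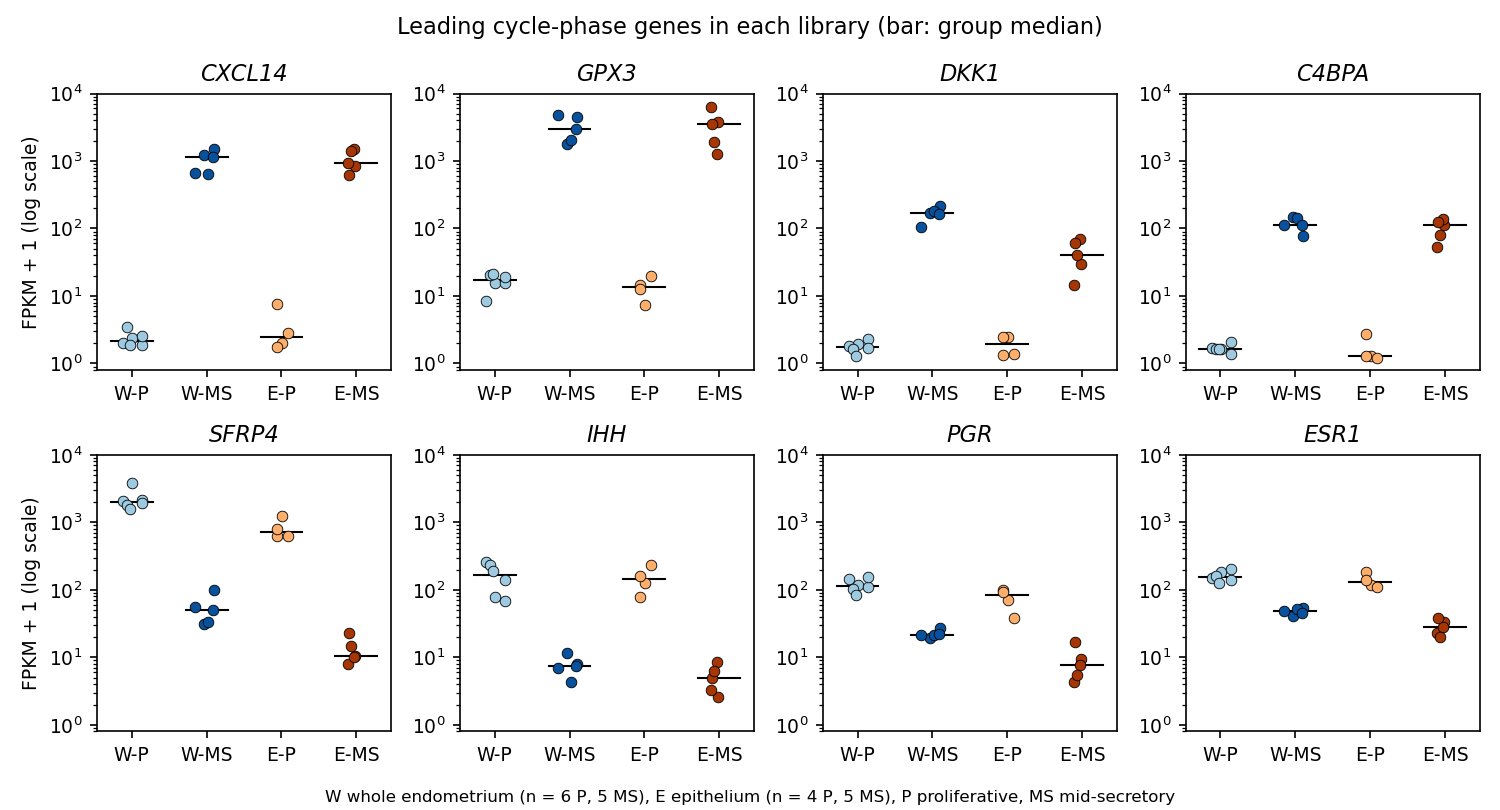
FPKM + 1 on a log axis for CXCL14, GPX3, DKK1, C4BPA, SFRP4, IHH, PGR and ESR1 in the 4 groups; each point is 1 library and each bar is the group median. In whole endometrium the mean of CXCL14 goes from 1.34 to 1042 FPKM and that of SFRP4 from 2241 to 52.7 FPKM between the proliferative and mid-secretory phases.

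Genes of growth fall together. All 36 tested members of the cell cycle list fall and 0 rise (median log2 change -2.02, camera adjusted p = 7.09e-28, and adjusted p = 0.0591 with an estimated correlation). The same 36 pass adjusted over the list alone. KIF20A, a kinesin of cytokinesis, and TOP2A change by -2.89 and -2.89, CCNB2 by -2.74 and TYMS by -2.67. In the list of genes described before as high in the proliferative phase 1 rose, 22 fell and 1 did not pass (median -2.51, camera adjusted p = 2.88e-17, and adjusted p = 1.23e-06 with an estimated correlation; 1 rose and 22 fell adjusted over the list alone), and its riser is PLA2G4F at 2.05. In the WNT list 5 rose, 15 fell and 12 did not pass (median -0.55, camera adjusted p = 6.66e-04, and adjusted p = 0.0190 with an estimated correlation; 5 rose and 17 fell adjusted over the list alone). Its antagonists go both ways, with SFRP1 at -3.35 and DKK3 at -2.62 beside the rise of DKK1.

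Genes described before as high in the receptive endometrium rise. In that list 35 rose, 3 fell and 0 did not pass (median 4.06, camera adjusted p = 6.48e-28, and adjusted p = 3.07e-05 with an estimated correlation), and the same numbers pass adjusted over the list alone. Beside CXCL14, GPX3 and DKK1 it holds LIF, an implantation cytokine, at 3.22. Counted as fallen are PAEP, whose listed 0 in all mid-secretory libraries does not give its level, SORD at -1.69 and SLC15A2 at -1.07, the last 2 named after their values were seen. The list of steroid receptors and progesterone targets splits: 13 rose, 9 fell and 8 did not pass (median 0.21, camera adjusted p = 0.553; 13 rose and 9 fell adjusted over the list alone). HSD17B2, which inactivates estradiol, rises from 1.76 ± 0.730 to 59.8 ± 16.8 FPKM (4.45, limma adjusted p = 1.24e-07), FKBP5, a chaperone of steroid receptors, by 3.04 (limma adjusted p = 1.22e-06), and the transcription factor FOXO1 by 2.74 (limma adjusted p = 1.65e-08). In the steroid metabolism list 5 rose, 0 fell and 13 did not pass (median 0.44, camera adjusted p = 0.0222, and adjusted p = 0.0591 with an estimated correlation; 5 rose and 0 fell adjusted over the list alone). Among the members are SRD5A3 at 2.32 and STAR at 2.26.

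Defence genes and metallothioneins rise. In the complement and antimicrobial list 14 rose, 3 fell and 10 did not pass (median 0.99, camera adjusted p = 3.68e-07, and adjusted p = 0.00234 with an estimated correlation; 16 rose and 5 fell adjusted over the list alone). CD55, which protects cells from complement, rises by 4.16, the defensin DEFB1 by 4.04 and CFD by 3.92. In the cytokine list 17 rose, 1 fell and 17 did not pass (median 0.69, camera adjusted p = 4.13e-05, and adjusted p = 0.155 with an estimated correlation; 17 rose and 1 fell adjusted over the list alone). The list includes CXCL13 at 4.23 and IL15 at 3.06. In the metallothionein list 8 rose, 1 fell and 1 did not pass (median 3.28, camera adjusted p = 6.47e-05, and adjusted p = 0.262 with an estimated correlation; 8 rose and 1 fell adjusted over the list alone). MT1G rises by 5.31 and MT1M by 5.23. These genes are near copies of each other, and how reads matching several of them were shared is not given in the sources used here. In the ion and solute transport list 13 rose, 8 fell and 11 did not pass (median 0.60, camera adjusted p = 0.0322, and adjusted p = 0.325 with an estimated correlation; 16 rose and 9 fell adjusted over the list alone). Members include the peptide transporter SLC15A1 at 5.25 and the water channel AQP3 at 4.79. That call is lost in 6 of 33 alternatives, all with a camera adjusted p near the threshold: with own groups only, array weights or the replicate block, and without whole proliferative replicate 1 (0.0599), whole mid-secretory replicate 2 (0.0527) or epithelium proliferative replicate 1 (0.0531).

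In the integrin and adhesion list 15 rose, 2 fell and 12 did not pass (median 0.88, camera adjusted p = 0.00222, and adjusted p = 0.0736 with an estimated correlation; 15 rose and 2 fell adjusted over the list alone). The tight junction gene CLDN4 rises by 3.48 and the cadherin CDH2 changes by -2.39. In the decidual list 14 rose, 1 fell and 4 did not pass (median 1.51, camera adjusted p = 1.54e-06, and adjusted p = 0.00743 with an estimated correlation; 16 rose and 1 fell adjusted over the list alone). IGFBP1, which decidual stroma secretes, rises by 3.92, SCARA5 by 4.47 and prolactin (PRL) by 1.75. The matrix and protease list shows no shift as a whole: 9 rose, 7 fell and 13 did not pass (median 0.11, or 0.07 without COL3A1, camera adjusted p = 0.652; 9 rose and 7 fell adjusted over the list alone). Members move both ways: MMP26, MMP11 and MMP7 fall, and the protease inhibitor TIMP3 rises by 3.65. In the TGF-beta and BMP list 10 rose, 5 fell and 12 did not pass (median 0.13, camera adjusted p = 0.257; 10 rose and 7 fell adjusted over the list alone). Members include LEFTY1, an inhibitor of nodal signalling, at 5.11 and GDF15 at 2.55.

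Markers of cell types move too. Lymphocyte and natural killer markers rise (14 rose, 0 fell and 4 did not pass; median 1.69, camera adjusted p = 4.13e-05, and adjusted p = 0.479 with an estimated correlation; 14 rose and 0 fell adjusted over the list alone), among them the cytotoxic granule genes GZMB at 3.75, GNLY at 3.64 and GZMA at 3.04. Macrophage markers rise (4 rose, 0 fell and 11 did not pass; median 0.84, camera adjusted p = 0.00685, and adjusted p = 0.601 with an estimated correlation; 4 rose and 0 fell adjusted over the list alone). CD68, a lysosomal protein, rises by 2.58. Mid-secretory replicate 2 has lymphocyte and macrophage medians of 2.36 and 3.02 on the log2 scale. Both lie inside the proliferative ranges of 1.74 to 2.85 and 2.85 to 3.54. The other mid-secretory libraries are at 3.15 to 4.79 and 4.19 to 4.72. No shift passes for epithelial (6 rose, 1 fell and 8 did not pass; median 0.50, camera adjusted p = 0.128), stromal (4 rose, 5 fell and 5 did not pass; 0.37, or 0.22 without COL3A1, 0.852), endothelial (0 rose, 0 fell and 13 did not pass; -0.11, 0.852) or smooth muscle markers (4 rose, 0 fell and 7 did not pass; 0.55, 0.104). The handling list of immediate early and heat shock genes rises a little (7 rose, 0 fell and 12 did not pass; median 0.28, camera adjusted p = 0.0217, and adjusted p = 0.557 with an estimated correlation; 7 rose and 0 fell adjusted over the list alone). IER3 rises by 2.72, ZFP36 by 2.26 and DUSP1 by 1.74. Without whole mid-secretory replicate 1 the epithelial and smooth muscle lists pass (camera adjusted p = 0.0405 and 0.0278). The smooth muscle list also passes with no filter and within the second code prefix (lowest camera adjusted p = 0.00425). Of the 28 lists 14 are called in whole endometrium, 11 up and 3 down, and 5 of these hold with an estimated correlation.

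**Figure D3:**
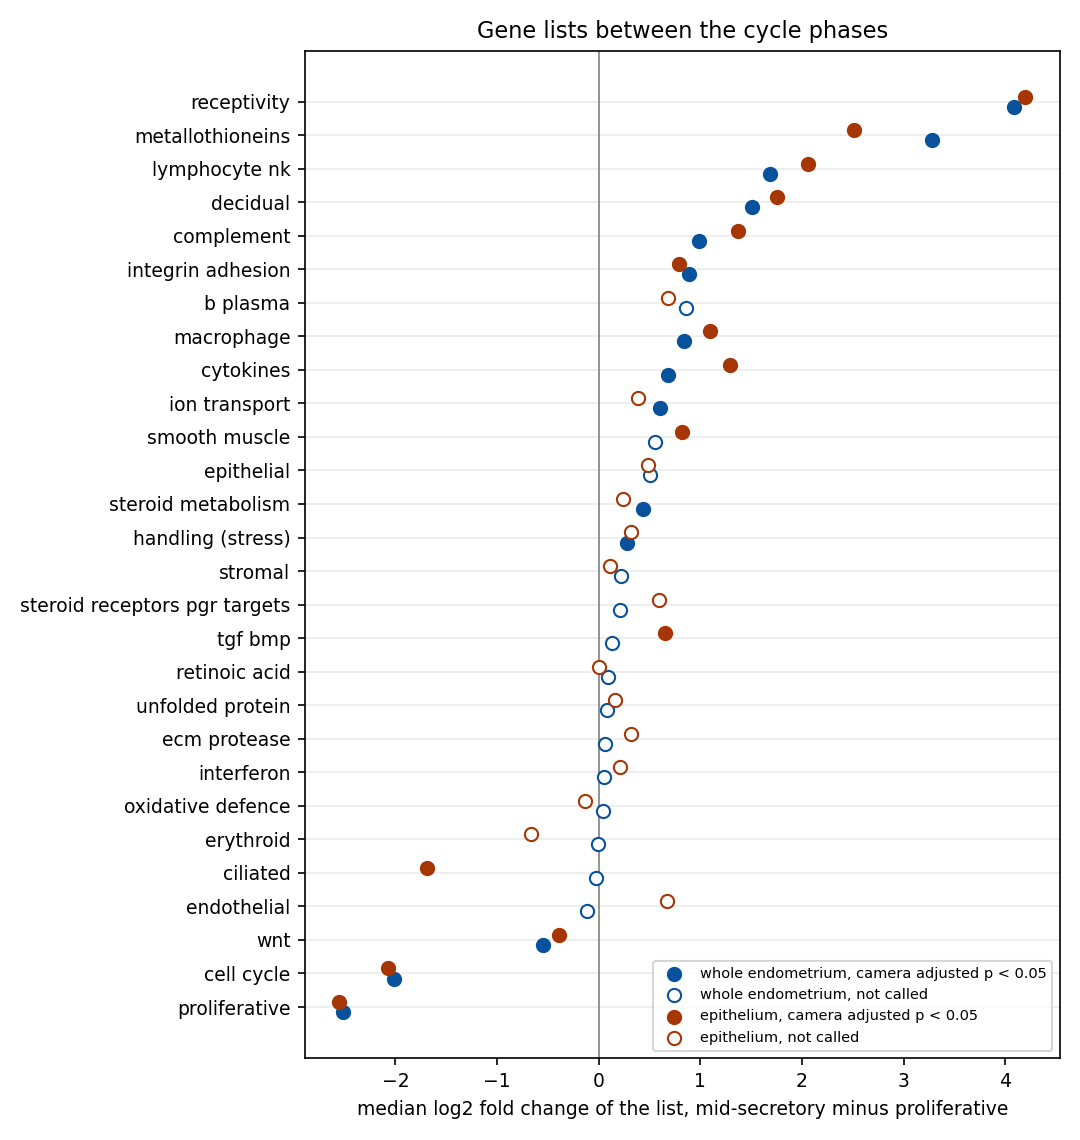
Median log2 fold change, mid-secretory over proliferative, of the tested members of each of the 28 gene lists, in whole endometrium and in epithelium. The medians shown leave out COL3A1, EEF1A1 and PAEP, which are listed at 0 in whole groups, while the camera tests include them. Each point is 1 list in 1 kind of sample, filled where the camera adjusted p is under 0.05. The receptivity list lies at 4.08 and 4.20, and the ciliated list at -0.03 in whole endometrium and -1.69 in epithelium.

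The epithelium libraries show the same leading changes: CXCL14, GPX3 and TCN1 rise and SFRP4, MMP26, SLC47A1 and IHH fall. PGR and ESR1 fall here as well. Beside these stand CYP3A5, a drug- and steroid-metabolising enzyme, the secretoglobin SCGB2A2 and IGFBP1, which rise, and KMO, an enzyme of tryptophan breakdown, which falls. Genes of motile cilia fall as a list (camera adjusted p = 3.68e-06), a call that is lost with an estimated correlation (adjusted p = 0.394). The epithelium libraries also hold stromal transcripts, with stromal markers at medians of -1.21 (proliferative) and -1.09 (mid-secretory) against whole endometrium. Which cells carry a change, such as that of SFRP4 or IGFBP1, was not tested.

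In epithelium 5220 of 15420 genes are called, 2602 higher and 2618 lower in the mid-secretory phase, and 2402 change at least 2-fold (1305 higher, 1097 lower). Within the first code prefix (4 and 3 libraries) 3898 are called, 2016 higher and 1882 lower; the second prefix holds 2 mid-secretory libraries and 0 proliferative ones. Own groups only gives 3293 and the handling list median as a covariate, chosen after the data were seen, 2948. CXCL14 rises from 2.57 ± 2.75 to 1062 ± 373 FPKM (mean ± SD, n = 4 and 5), a log2 change of 8.41 (SE 0.37, limma adjusted p = 2.06e-12), and GPX3 from 12.6 ± 5.22 to 3372 ± 1999.5 FPKM (7.82, SE 0.42). TCN1 rises by 6.66 (limma adjusted p = 3.56e-09), C2CD4A by 6.06, GAST by 6.37 and COMP, a matrix glycoprotein, by 6.05. CYP3A5 rises from 0.733 ± 0.450 to 216 ± 213 FPKM (6.45, limma adjusted p = 7.95e-09). IGFBP1 rises from 0.999 ± 0.900 to 393 ± 554 FPKM (6.02, limma adjusted p = 5.84e-05), with an SD above its mean, and SCGB2A2 by 6.23 (SE 0.83, limma adjusted p = 8.73e-06). PAEP and EEF1A1, each listed at 0 in every library of 1 of these groups, get no fold change.

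SFRP4 falls from 827 ± 297 to 12.3 ± 6.04 FPKM in epithelium, a log2 change of -6.00 (SE 0.34, limma adjusted p = 1.07e-10), and SLC47A1 from 79.0 ± 25.7 to 0.664 ± 0.206 FPKM, a change of -5.52 (SE 0.21, limma adjusted p = 2.88e-13). KMO goes from 41.8 ± 15.1 to 0.691 ± 0.356 FPKM, a change of -4.61 (SE 0.28, limma adjusted p = 3.28e-10). MMP26 changes by -5.67, MMP7 by -4.26, TRH by -4.63, SPDEF by -5.05 and the protease inhibitor SERPINA5 by -4.19. IHH goes from 149 ± 66.9 to 4.12 ± 2.39 FPKM (-4.89, limma adjusted p = 4.34e-08). PGR goes from 75.6 ± 28.1 to 7.76 ± 4.99 FPKM (-3.20, limma adjusted p = 2.49e-07) and ESR1 from 136 ± 32.6 to 27.6 ± 7.45 FPKM (-2.28, limma adjusted p = 3.42e-08). The differences between these PGR and ESR1 changes and those in whole endometrium, -0.83 and -0.56, are not called (limma adjusted p = 0.626 and 0.542).

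The growth lists fall in epithelium too. In the cell cycle list 0 rose, 35 fell and 1 did not pass (median -2.07, camera adjusted p = 1.36e-23, and adjusted p = 0.0931 with an estimated correlation; 0 rose and 36 fell adjusted over the list alone). Among the members are UBE2C, which drives exit from mitosis, at -2.88 and AURKB at -2.82. In the list of proliferative phase genes 0 rose, 22 fell and 2 did not pass (median -2.55, camera adjusted p = 1.05e-15, and adjusted p = 2.41e-06 with an estimated correlation; 0 rose and 22 fell adjusted over the list alone). In the WNT list 3 rose, 12 fell and 17 did not pass (median -0.39, camera adjusted p = 0.0144, and adjusted p = 0.0931 with an estimated correlation; 3 rose and 12 fell adjusted over the list alone). The list includes DKK1 at 4.35 and PORCN, needed to secrete WNT proteins, at -2.69. The receptivity list rises, where 35 rose, 3 fell and 0 did not pass, PAEP again counted as fallen on its listed 0 (median 4.18, camera adjusted p = 8.27e-25, and adjusted p = 6.38e-05 with an estimated correlation; 35 rose and 3 fell adjusted over the list alone). The list of steroid receptors and progesterone targets splits again (11 rose, 9 fell and 10 did not pass; median 0.59, camera adjusted p = 0.373; 14 rose and 9 fell adjusted over the list alone). Members include HSD17B2 at 3.61, FKBP5 at 3.03 and FOXO1 at 2.66.

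Complement and antimicrobial genes rise in epithelium (16 rose, 2 fell and 9 did not pass; median 1.37, camera adjusted p = 3.68e-06, and adjusted p = 0.00575 with an estimated correlation; 16 rose and 3 fell adjusted over the list alone). Members include C4BPA at 5.97, CD55 at 3.94 and DEFB1 at 3.48. Cytokine genes rise (21 rose, 3 fell and 11 did not pass; median 1.29, camera adjusted p = 1.86e-05, and adjusted p = 0.158 with an estimated correlation; 22 rose and 3 fell adjusted over the list alone). CCL20, which attracts lymphocytes and dendritic cells, rises by 3.41 and IL15 by 2.67, while CSF3 changes by -3.13. The TGF-beta and BMP list rises (13 rose, 3 fell and 11 did not pass; median 0.66, camera adjusted p = 0.0233, and adjusted p = 0.285 with an estimated correlation; 14 rose and 3 fell adjusted over the list alone), led by LEFTY2 at 4.33 and TGFB2 at 2.83; the camera call is lost without proliferative replicate 3 (adjusted p = 0.0665), without mid-secretory replicate 4 (0.0582) and with handling genes as a covariate (0.128). Integrin and adhesion genes rise (14 rose, 1 fell and 14 did not pass; median 0.79, camera adjusted p = 6.38e-04, and adjusted p = 0.0674 with an estimated correlation; 14 rose and 2 fell adjusted over the list alone). Among the members are CLDN1 at 2.52 and CD44 at 2.42. Metallothioneins rise (7 rose, 1 fell and 2 did not pass; median 2.51, camera adjusted p = 0.00605, and adjusted p = 0.456 with an estimated correlation; 7 rose and 1 fell adjusted over the list alone). MT1H rises by 5.04. Mid-secretory replicates 3 and 5 stand apart in the cytokine, TGF-beta and metallothionein lists. Their cytokine medians are 3.67 and 3.33 on the log2 scale against 4.49 to 4.90 in the other libraries (proliferative 2.44 to 3.63). For the TGF-beta list they are 2.70 and 2.60 against 3.14 to 3.66 (proliferative 2.42 to 2.96). Metallothionein medians are higher there, 7.47 and 8.31 against 5.05 to 5.78 (proliferative 2.54 to 4.42).

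The transport list does not shift as a whole in epithelium (14 rose, 10 fell and 8 did not pass; median 0.38, camera adjusted p = 0.212; 14 rose and 11 fell adjusted over the list alone). SLC15A1 rises by 5.96, SLC3A1 by 5.57 and the glutamate transporter SLC1A1 by 4.98. Nor do the steroid metabolism list (4 rose, 1 fell and 13 did not pass; 0.24, 0.308) and the matrix and protease list (10 rose, 4 fell and 15 did not pass; 0.31, 0.576; 10 rose and 5 fell adjusted over the list alone), where MMP10 is at 3.88 and TIMP3 at 3.56.

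Lists of other cell types rise in the epithelium libraries, not all alike between libraries. In the lymphocyte and natural killer list 15 rose, 0 fell and 3 did not pass (median 2.06, camera adjusted p = 2.70e-06, and adjusted p = 0.377 with an estimated correlation; 17 rose and 0 fell adjusted over the list alone). The list includes GNLY at 4.38, GZMB at 3.92 and GZMA at 3.58. In the decidual list 12 rose, 1 fell and 6 did not pass (median 1.75, camera adjusted p = 5.30e-06, and adjusted p = 0.0122 with an estimated correlation; 14 rose and 2 fell adjusted over the list alone). PRL rises by 3.07. Macrophage markers (5 rose, 0 fell and 10 did not pass; median 1.10, camera adjusted p = 7.64e-04, and adjusted p = 0.504 with an estimated correlation; 11 rose and 0 fell adjusted over the list alone) and smooth muscle markers (4 rose, 0 fell and 7 did not pass; median 0.82, camera adjusted p = 0.00323, and adjusted p = 0.377 with an estimated correlation; 7 rose and 0 fell adjusted over the list alone) rise as well. Mid-secretory replicates 3 and 5 stand apart in all of these lists: they have lymphocyte medians of 2.23 and 2.02 on the log2 scale against 4.07 to 4.34 in the other 3. Their macrophage medians are 2.14 and 2.30 against 3.43 to 4.57, inside the proliferative range of 1.63 to 2.80. Their decidual medians are 3.51 and 3.54 against 4.16 to 5.10, and their smooth muscle medians 3.47 and 3.53 against 3.87 to 4.93. Both are above the proliferative ranges (1.72 to 2.14 and 3.03 to 3.42). Replicate 3 holds 21.1% of its FPKM in 10 genes, against 7.25% to 10.5% in the other mid-secretory epithelium libraries. Replicate 5 has the lowest relative depth (0.325), but replicate 2, which does not stand apart with them, is also low (0.553). Whether these traits bear on the medians was not tested. Epithelial (5 rose, 2 fell and 8 did not pass; 0.48, 0.212), stromal (5 rose, 4 fell and 5 did not pass; -0.22, 0.630) and endothelial markers (3 rose, 0 fell and 10 did not pass; 0.67, 0.0778; 6 rose and 0 fell adjusted over the list alone) do not pass by camera adjusted p, nor does the handling list (5 rose, 0 fell and 14 did not pass; 0.32, 0.0659). The stromal median is 0.11 without COL3A1, and its test points down. The endothelial list passes without mid-secretory replicate 3 or proliferative replicate 1 (camera adjusted p = 0.0155 and 0.0138), within the first code prefix (0.0394) and with no filter (0.0369). The handling list passes without mid-secretory replicates 3 or 5 or proliferative replicate 4 (0.0247, 0.0249 and 0.00459), with no filter (0.0279), with the replicate block (0.0377) and without the 3 lowest-weight epithelium libraries (0.0469). Of the 28 lists 14 are called in epithelium, 10 up and 4 down, and 4 hold with an estimated correlation.

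Ciliated cell markers fall in epithelium: 0 rose, 13 fell and 3 did not pass (median -1.69, camera adjusted p = 3.68e-06, and adjusted p = 0.394 with an estimated correlation; 0 rose and 15 fell adjusted over the list alone). C20orf85, PIFO, ZMYND10 and RSPH1, all genes of motile cilia, change by -2.72, -2.50, -2.36 and -2.31. In whole endometrium 0 rose, 0 fell and 16 did not pass (median -0.03, camera adjusted p = 0.852). The difference itself was tested with the phase by tissue contrast, where the list median is -1.69 (camera adjusted p = 3.50e-14, and adjusted p = 0.504 with an estimated correlation). In that contrast 0 of the 16 members are called over all genes, and 13 fell adjusted over the list alone. Within the second code prefix the list falls in whole endometrium too (median -0.75, camera adjusted p = 0.00374), and within the first it does not (0.47, adjusted p = 0.422). All 4 epithelium proliferative libraries have a higher relative depth (1.20 to 1.73 times the median library) than the 5 epithelium mid-secretory ones (0.325 to 1.17).

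Many phase changes are shared by both kinds of sample. Of the genes called, 1760 are higher in both and 1668 lower in both, where 408 and 400 would be expected if the calls were independent (Fisher's exact odds ratios 38.6 and 30.9). Whole endometrium contains epithelium, whose markers there reach 0.781 and 0.818 of their level in epithelium libraries, and both contrasts use one estimate of spread. Some overlap is therefore built in, and the excess does not show that separate cell compartments change alike. The 3428 shared genes are part of 6561 called in either; with a 2-fold minimum 1510 are shared, and within the first code prefix 2154. Across the 15420 genes the log2 changes correlate with Pearson's r 0.84 and Spearman's rho 0.80, although genes are not independent replicates. Of the genes called in whole endometrium, 97.5% have the same sign in epithelium, and of those called in epithelium 95.4% have it in whole endometrium. Called in both with opposite signs are 5 genes. Among these, named after their values were seen, are AHCY, which recycles S-adenosylhomocysteine (0.91 in whole endometrium, -0.63 in epithelium), the transcription factor SRF (0.70, -0.62), Myopodin, an actin-binding protein (-1.02, 1.34), and LOC100288911 (-0.65, 0.66).

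A direct test of the difference between the phase changes calls 35 genes, 19 with a higher and 16 with a lower change in epithelium. PCK1, which makes phosphoenolpyruvate in gluconeogenesis, rises in epithelium from 0.390 ± 0.359 to 22.5 ± 14.7 FPKM (3.85) and is not called in whole endometrium (0.28); the difference is 3.57 (SE 0.44, limma adjusted p = 2.55e-04). PTHLH, a parathyroid hormone-like peptide, falls in whole endometrium (-2.43) and is not called in epithelium (0.08), a difference of 2.51 (SE 0.37, limma adjusted p = 0.00310). CBLN1 changes by -3.56 in whole endometrium and -1.37 in epithelium (difference 2.19, limma adjusted p = 0.0106). The acute-phase inhibitor SERPINA3 rises in whole endometrium (3.11, against -0.71 in epithelium), a difference of -3.82 (SE 0.72, limma adjusted p = 0.0215). SOCS3, which restrains cytokine signalling, rises by 2.87 in whole endometrium, against a change of 0.58 in epithelium (difference -2.29, limma adjusted p = 0.0215), and the transcription factor CEBPD by 3.48, against 1.27 (difference -2.20, limma adjusted p = 0.0274). Myopodin (2.36, limma adjusted p = 0.0434) and CSF3 (-2.59, limma adjusted p = 0.0215) complete the named genes. CSF3 is listed at 0 in all whole mid-secretory libraries, which does not give its level, so its difference is uncertain. ZFP36 at -1.94 and BCL6 at -1.78, named after their values were seen, change with SOCS3 and CEBPD in direction, and ZFP36 is on the handling list.

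The count of 35 rests on few libraries: without epithelium proliferative replicate 2 it is 74 (20 with a higher and 54 with a lower change in epithelium), without epithelium proliferative replicate 3 it is 17 (11 and 6), and within the first code prefix it is 12 (6 and 6). With a pseudocount of 0.1 it is 20 and without the 3 lowest-weight epithelium libraries 15. At an unadjusted p under 0.05 it is 1370 genes. With each library left out in turn PCK1, PTHLH and CBLN1 stay called. SERPINA3 loses its call without 3 of the libraries (limma adjusted p up to 0.0587), SOCS3 without 2 (up to 0.0578), CSF3 without 1 (0.0578), CEBPD without 8 (up to 0.0755) and Myopodin without 14 (up to 0.0956). Beside the ciliated list, metallothioneins rise by less in epithelium (median difference -1.09, camera adjusted p = 0.0182, and adjusted p = 0.709 with an estimated correlation), and endothelial markers are higher by 0.60 (camera adjusted p = 0.00301, and adjusted p = 0.709 with an estimated correlation). Over all genes 0 metallothionein and 0 endothelial markers are called, and 0 and 0 adjusted over the list alone. The metallothionein call is lost without any 1 of 7 libraries (whole proliferative replicate 1, whole mid-secretory replicates 2 and 3, epithelium proliferative replicate 4, epithelium mid-secretory replicates 1, 2 and 4; camera adjusted p 0.0517 to 0.209), and the endothelial call without epithelium mid-secretory replicate 2 (0.182) or epithelium proliferative replicate 2 (0.107), or without the 3 lowest-weight epithelium libraries (0.109). The ciliated call stays without each single library, at camera's preset correlation. Not called here but higher in some alternatives are interferon genes (without any 1 of 7 libraries), lymphocyte markers (array weights, first code prefix, a pseudocount of 0.1, or without any 1 of 3 libraries) and macrophage markers (array weights, first code prefix, or without any 1 of 3 libraries). Within the first code prefix cell cycle genes are called higher (camera adjusted p = 0.00180), and complement genes (0.0466) and red blood cell markers (0.00551) lower. The handling list is called lower without epithelium proliferative replicate 1 and with its own median as a covariate.

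Epithelium libraries differ from whole endometrium most in immediate early genes, in both phases. FOSB and FOS, parts of the AP-1 factor, ATF3, a stress-induced factor, ZFP36, which shortens the life of mRNAs, and NR4A1, an early-response nuclear receptor, are low in whole endometrium and many times higher in epithelium. Cytokines of acute responses (IL8, CXCL2) are higher with them. Stromal genes such as DCN and LUM, both small matrix proteoglycans, and COL1A1 are lower in epithelium.

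In the proliferative phase 3875 genes are called between epithelium and whole endometrium, 671 higher and 3204 lower in epithelium (17.3% higher), 942 of them at least 2-fold. The split depends on the scaling: the median log2 change of all genes is -0.24 in the FPKM as listed, median-of-ratios scaling gives 1875 calls (1072 higher, 803 lower) and quantile normalization 2328 (1095 higher, 1233 lower). Within the first code prefix 2796 are called; all 4 epithelium libraries carry that prefix. FOSB goes from 0.901 ± 0.602 FPKM in whole endometrium to 817 ± 361 FPKM in epithelium (mean ± SD, n = 6 and 4), a log2 difference of 8.71 (SE 0.29, limma adjusted p = 4.46e-14). FOS goes from 6.83 ± 2.08 to 1589 ± 628 FPKM (7.62), ATF3 differs by 6.43 (limma adjusted p = 7.71e-11) and ZFP36 by 6.40 (limma adjusted p = 3.85e-13). Lower are CBLN1 at -2.45 (limma adjusted p = 2.25e-06), TMEM185A at -2.70 (listed at 0 in 3 of the 4 epithelium libraries, which does not give its level), the inositol phosphate kinase PPIP5K1 at -2.57 and BX647608 at -2.55.

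In the mid-secretory phase 4418 are called, 756 higher and 3662 lower in epithelium (17.1% higher, median of all genes -0.24), 1129 of them at least 2-fold. Median-of-ratios scaling gives 2713 (1399 higher, 1314 lower), quantile normalization 2830 (1211 higher, 1619 lower) and the first code prefix alone 1990 (400 higher, 1590 lower). The second prefix alone, with 2 libraries of each kind, gives 35 and another split, 34 higher and 1 lower, while the median of all genes is -0.23 there. FOSB goes from 0.976 ± 0.481 to 851 ± 294 FPKM (mean ± SD, n = 5 and 5), a difference of 8.72 (SE 0.29, limma adjusted p = 2.89e-14), and NR4A1 from 5.86 ± 3.92 to 999 ± 373 FPKM (7.27, limma adjusted p = 2.11e-12). The neutrophil chemokine IL8 goes from 0.553 ± 0.133 to 252 ± 208 FPKM (6.58, limma adjusted p = 4.36e-06). Lower are PAGE4 at -2.76 (limma adjusted p = 1.99e-04), the secreted phospholipase PLA2G2A at -2.45, the angiogenesis inhibitor SERPINF1 at -2.45, BX647608 at -2.71 and PPIP5K1 at -2.47.

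The handling list leads both comparisons. In the proliferative phase 18 rose, 0 fell and 1 did not pass (median 4.17, camera adjusted p = 2.48e-64, and adjusted p = 4.05e-05 with an estimated correlation), and in the mid-secretory phase 19 rose, 0 fell and 0 did not pass (median 4.14, camera adjusted p = 2.63e-57, and adjusted p = 8.40e-05 with an estimated correlation). All 19 rose adjusted over the list alone in both phases. Cytokine genes move with it: 15 rose, 5 fell and 15 did not pass in the proliferative phase (median 0.72, camera adjusted p = 1.08e-08, and adjusted p = 0.124 with an estimated correlation) and 12 rose, 3 fell and 20 did not pass in the mid-secretory phase (median 0.46, camera adjusted p = 1.33e-07, and adjusted p = 0.141 with an estimated correlation). CXCL2 differs by 5.15 and 6.54, and IL8 by 5.18 and 6.58. With the handling list median as a covariate, chosen after the data were seen, 1 gene is called in each phase; this covariate lies close to the tissue difference itself.

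**Figure D4:**
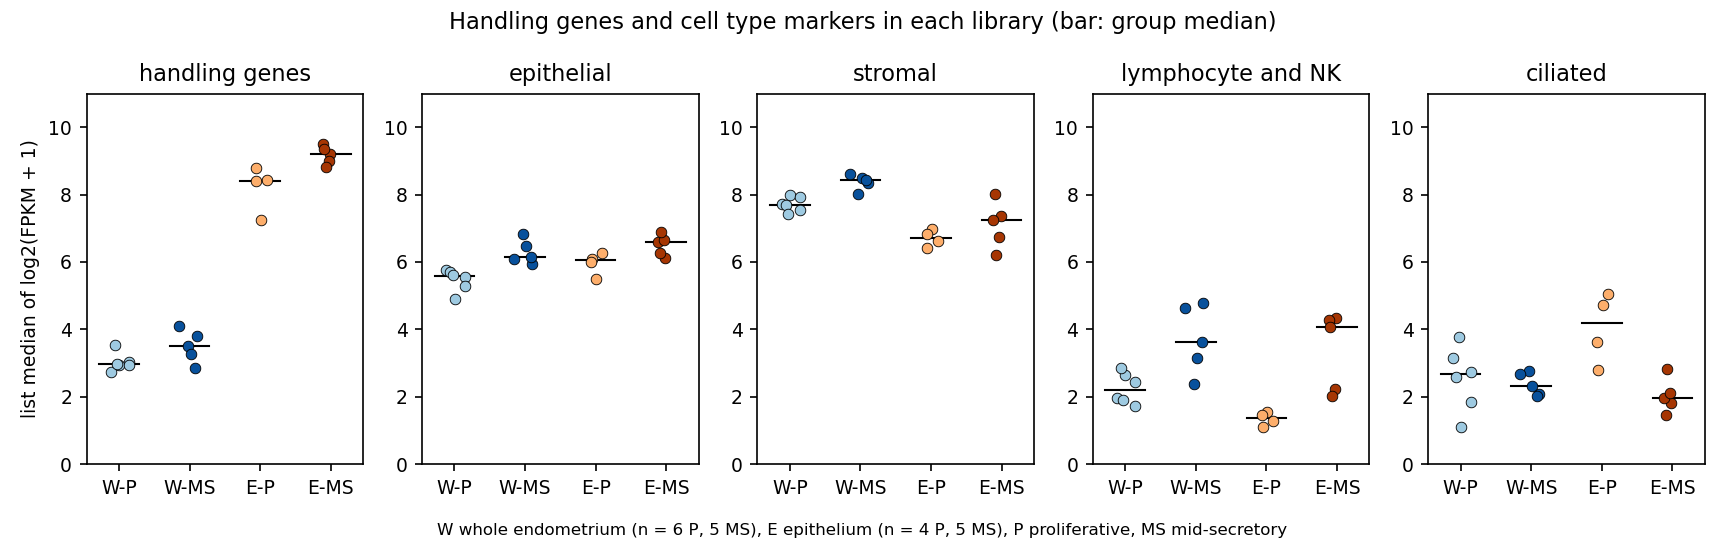
Median log2(FPKM + 1) of the members of the handling, epithelial, stromal, lymphocyte and natural killer, and ciliated lists in each library of the 4 groups; each point is 1 library and each bar is the group median. The handling list differs between epithelium and whole endometrium by a median log2 change of 4.17 in the proliferative and 4.14 in the mid-secretory phase.

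Markers of cell types differ between the kinds of sample. Epithelial markers are higher in epithelium by a median of 0.32 in the proliferative phase (3 rose, 0 fell and 12 did not pass; camera adjusted p = 5.11e-06, and adjusted p = 0.178 with an estimated correlation) and 0.27 in the mid-secretory phase (4 rose, 0 fell and 11 did not pass; camera adjusted p = 2.06e-04, and adjusted p = 0.281 with an estimated correlation). ELF3, an epithelial transcription factor also induced by inflammatory signals, differs by 3.18 and 2.60, KRT18 by 1.25 and 0.73, and KRT8 by 1.26 and 1.01, of which the second does not pass (limma adjusted p = 0.0240 and 0.0559). Stromal markers are lower, with medians of -1.21 (1 rose, 11 fell and 2 did not pass; camera adjusted p = 0.0356, and adjusted p = 0.560 with an estimated correlation) and -1.09 (0 rose, 11 fell and 3 did not pass; camera adjusted p = 5.83e-04, and adjusted p = 0.281 with an estimated correlation). The one that rose is COL3A1, listed at 0 in the 6 whole proliferative libraries. DCN and LUM differ by -1.80 and -1.82 in the proliferative phase, and COL1A1 by -1.18 and -1.20. Ciliated markers are higher in proliferative epithelium (11 rose, 0 fell and 5 did not pass; median 1.42, camera adjusted p = 4.58e-13, and adjusted p = 0.178 with an estimated correlation) and not called in the mid-secretory phase (-0.32, camera adjusted p = 0.749). Macrophage markers are lower in epithelium in the proliferative phase (0 rose, 9 fell and 6 did not pass; median -1.13, camera adjusted p = 0.00429, and adjusted p = 0.651 with an estimated correlation). In the mid-secretory phase they point the same way and do not pass (0 rose, 5 fell and 10 did not pass; -0.97, camera adjusted p = 0.153), but pass under median-of-ratios scaling (0.0248), quantile normalization (0.0358), no filter (0.0459), the second code prefix alone (5.62e-06) and without any 1 of 3 libraries. Lymphocyte and natural killer markers do not pass in the proliferative phase (0 rose, 3 fell and 15 did not pass; -0.93, camera adjusted p = 0.287), but are called lower under median-of-ratios scaling (0.0121), quantile normalization (0.01998) with own groups only (0.00464) and with the handling covariate, given below. In the mid-secretory phase they are not called (-0.45, camera adjusted p = 0.908) and pass with that covariate alone. The numbers that rose and fell adjusted over the list alone in the proliferative phase are 3 and 0 (epithelial), 1 and 12 (stromal), 15 and 0 (ciliated), 0 and 13 (macrophage), 0 and 3 (lymphocyte and natural killer), 17 and 5 (cytokines). In the mid-secretory phase they are 4 and 0 (epithelial), 0 and 12 (stromal), 0 and 0 (ciliated), 0 and 5 (macrophage), 0 and 0 (lymphocyte and natural killer), 15 and 3 (cytokines).

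Pathway lists differ less. Camera compares a list with all other genes, whose median is -0.24 in each phase, so a list can be called up with few members risen. In the proliferative phase it places the receptivity list above the other genes (6 rose, 2 fell and 30 did not pass; median 0.17, camera adjusted p = 1.70e-04, and adjusted p = 0.124 with an estimated correlation), and the metallothionein list (1 rose, 0 fell and 9 did not pass; median 0.79, camera adjusted p = 5.10e-04, and adjusted p = 0.376 with an estimated correlation). Ion transport (2 rose, 1 fell and 29 did not pass; median 0.14, camera adjusted p = 3.52e-04, and adjusted p = 0.124 with an estimated correlation) and integrin genes (2 rose, 5 fell and 22 did not pass; median 0.11, camera adjusted p = 0.0356, and adjusted p = 0.265 with an estimated correlation) lie above the other genes too. WNT genes (0 rose, 15 fell and 17 did not pass; median -0.51, camera adjusted p = 0.0470, and adjusted p = 0.178 with an estimated correlation) are lower. So are interferon genes (1 rose, 14 fell and 15 did not pass; median -0.59, camera adjusted p = 0.0470, and adjusted p = 0.610 with an estimated correlation). In the mid-secretory phase the receptivity list (5 rose, 5 fell and 28 did not pass; median 0.11, camera adjusted p = 0.00805, and adjusted p = 0.281 with an estimated correlation) and the integrin list (2 rose, 1 fell and 26 did not pass; median 0.13, camera adjusted p = 0.00203, and adjusted p = 0.141 with an estimated correlation) lie above the other genes, and so do endothelial markers (0 rose, 0 fell and 13 did not pass; median 0.24, camera adjusted p = 0.0101, and adjusted p = 0.628 with an estimated correlation). Retinoic acid genes are lower (0 rose, 10 fell and 12 did not pass; median -0.56, camera adjusted p = 0.0283, and adjusted p = 0.281 with an estimated correlation). The TGF-beta and BMP list has a median of -0.03, a mean of 0.19 and a test pointing up (4 rose, 6 fell and 17 did not pass; camera adjusted p = 0.0283, and adjusted p = 0.281 with an estimated correlation). Under median-of-ratios and quantile scaling its median is 0.22 and 0.18. Adjusted over the list alone the numbers that rose and fell in the proliferative phase are 5 and 2 (receptivity), 1 and 0 (metallothioneins), 1 and 1 (ion transport), 2 and 5 (integrins), 0 and 16 (WNT), 1 and 16 (interferon), and in the mid-secretory phase 5 and 5 (receptivity), 2 and 1 (integrins), 0 and 0 (endothelial), 0 and 11 (retinoic acid), 5 and 6 (TGF-beta). With an estimated correlation the handling list alone holds in each phase. Leaving out single libraries ends the proliferative calls of the integrin (4 libraries, camera adjusted p up to 0.131), interferon (9, up to 0.178), WNT (7, up to 0.110) and stromal lists (3, up to 0.0894), and the mid-secretory calls of the retinoic acid (2, up to 0.0569), TGF-beta (3, up to 0.0974) and endothelial lists (1, 0.193). Other alternatives end list calls too. The proliferative integrin call is lost with no filter (camera adjusted p = 0.218), median-of-ratios scaling (0.157), quantile normalization (0.141), the first code prefix alone (0.0731) and the replicate block (0.0614). The proliferative interferon call is lost with the first code prefix alone (0.213), own groups only (0.0978), code prefix as a covariate (0.0951), the replicate block (0.0919), array weights (0.0825) and a pseudocount of 0.1 (0.0504). The WNT call is lost without the 3 lowest-weight epithelium libraries (0.140), with array weights (0.0838), code prefix as a covariate (0.0759), a pseudocount of 0.1 (0.0541) and the replicate block (0.0516). In the mid-secretory phase the receptivity call is lost with median-of-ratios scaling (0.0744), quantile normalization (0.0685), the second code prefix alone (0.0624) and no filter (0.0603). The TGF-beta call is lost with median-of-ratios scaling (0.0848), no filter (0.0830), quantile normalization (0.0726) and the first code prefix alone (0.0574). The retinoic acid call is lost with the second code prefix alone (0.119), no filter (0.0577) and own groups only (0.0526), and the endothelial call with the second code prefix alone (0.373) and without the 3 lowest-weight epithelium libraries (0.221). The cell cycle list does not pass in the proliferative phase (0 rose, 8 fell and 28 did not pass; median -0.42, camera adjusted p = 0.0770), but is called lower in 10 of 32 alternatives: both scalings, no filter, own groups only, array weights, the first code prefix alone and without any 1 of 4 libraries (lowest 0.00596). Retinoic acid genes are called lower there under both scalings (0.0457 and 0.0344), and mid-secretory ion transport is called up in 7 of 33 alternatives (lowest 0.0157). The handling covariate, which lies close to the tissue difference itself, ends most list calls in each phase. It turns the mid-secretory receptivity and cytokine lists to lower (medians -1.83 and -1.34, camera adjusted p = 0.00856 and 0.0255). It also makes new calls: lymphocyte, decidual and unfolded protein lists lower in both phases (lymphocyte medians -5.02 and -5.03, camera adjusted p = 3.77e-11 and 1.13e-09), and in the mid-secretory phase macrophage, interferon (1.23e-04) and oxidative defence lists lower and ciliated markers higher.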

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

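The tests of handling genes, of genes listed at 0, of a fall of cilia genes in the tissue and of shuffled residuals were chosen after the result was seen.

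Immediate early and heat shock genes stand far higher in epithelium than in whole endometrium in both phases. Scaling between libraries is argued against, since after median-of-ratios scaling the lower of the medians is still 4.41 on the log2 scale. Epithelium that carries these transcripts in the tissue at the level of the epithelium libraries is argued against, since whole endometrium would then hold far more of them: epithelial markers there reach 0.781 and 0.818 of their level in epithelium libraries, but the handling genes reach a median of 0.0377 and 0.0597 of what that share needs. Induction by handling while the epithelium was separated may be the cause and cannot be told apart from other changes between sampling and RNA extraction: 18 of the 19 genes, 3 of the 4 heat shock genes among them, have no overlap between the groups in both phases, but any such cause gives that. No epithelium library prepared another way is in this series.

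Some abundant genes are listed at exactly 0 in whole groups. COL3A1 is at 0 in all 6 whole proliferative libraries and at 833 to 1561 FPKM in whole mid-secretory, 391 to 971 in epithelium proliferative and 297 to 824 in epithelium mid-secretory ones. EEF1A1, which every cell needs for translation, is at 0 in 15 libraries and at 582 to 1902 FPKM in the epithelium mid-secretory ones. That COL3A1 is truly absent from the whole proliferative tissue is argued against by the epithelium of the same phase, which carries less stroma and lists at least 391 FPKM, and an estimate that failed at very high abundance may be the source, which was not tested. PAEP is at 20.8 to 218 and 10.2 to 74.4 FPKM in the proliferative groups and at 0 in all 10 mid-secretory libraries. Of 4495 other genes at 10 FPKM or more in all proliferative libraries, 0 fall under 0.1 FPKM (the nearest, NPAS3, reaches 0.772). These values alone cannot tell a fall below detection from a failed estimate, since a 0 in this table does not give the level. PAEP is on the list of genes described before as high in the receptive endometrium. COL3A1 shows that a listed 0 need not mean absence. The 0 of PAEP is therefore not read as a fall.

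Ciliated markers fall in epithelium (median -1.69) and not in whole endometrium (-0.03), a difference of -1.69 in the phase by tissue contrast; with an estimated correlation the camera adjusted p is 0.394 in epithelium and 0.504 for the difference, and 0 of 16 members are called in the contrast. A single epithelium proliferative library and scaling are argued against as the source of the list median, which closest to 0 is -1.40 without 1 of these libraries and -1.69 under scaling. The camera call also stays in these fits, but at the preset correlation, so it does not settle how far the fall rests on few libraries. Ciliated medians on the log2 scale are 4.74, 2.80, 5.04 and 3.63 in epithelium proliferative replicates 1 to 4. They are 1.46 to 2.82 in epithelium mid-secretory and 1.10 to 3.76 in whole proliferative libraries. A fall in the epithelium of the tissue by phase that whole endometrium shares cannot be told apart: relative to epithelial markers the ciliated median changes by -0.98 in whole endometrium and -2.57 in epithelium, -1.59 apart (SE 0.662, or -2.40 standard errors), but without epithelium proliferative replicate 1 by -1.21 (-1.76 standard errors) and without replicate 3 by -1.36 (-1.68). A differing share of ciliated cells taken up in the proliferative and mid-secretory preparations of epithelium may play a part and was not tested.

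Other splits of the same libraries, 100 per comparison with the real one included, ask whether chance gives as many calls. With phase labels shuffled, chance is excluded for the phase calls of whole endometrium (4774 against at most 555 in another split, 1 of 100 as large) and of epithelium (5220 against 3493, 1 of 100). The shared calls were 3428 against 0 (1 of 100), but the shuffle removes both phase effects. It therefore does not test whether 2 real phase changes share more genes than unrelated ones would. Chance is not excluded for the number of lists called in whole endometrium (14 against up to 16, 11 of 100 as large) and in epithelium (14 against 18, 15 of 100). For the 35 phase by tissue calls shuffled phase labels (3 of 100 as large, highest other 742) and shuffled tissue labels (6 of 100, highest other 4741) decide nothing, since they remove the phase or tissue effect itself and do not hold the 2 phase changes equal. With the residuals of a fit of equal phase changes shuffled instead, 3 of 100 splits were as large, the real one included (highest other 1148). That test pools residuals over libraries of unequal spread (array weights 0.252 to 5.01), so it does not exclude chance for these calls. Splits with many times the real count point to a structure of the samples, which was not tested further. For tissue chance is excluded in the proliferative phase (3875 against 1545, 1 of 100) and in the mid-secretory phase (4418 against 3621, 1 of 100).

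A direct test calls the phase changes of some genes and lists as different between epithelium and whole endometrium. Chance is not excluded for the 35 gene calls. Leaving out single libraries ends the call of Myopodin for 14 of them, CEBPD for 8, SERPINA3 for 3, SOCS3 for 2 and CSF3 for 1. PCK1, PTHLH and CBLN1 keep theirs. The differences, epithelium minus whole, are 3.57 for PCK1, 2.51 for PTHLH, 2.36 for Myopodin, 2.19 for CBLN1, -3.82 for SERPINA3, -2.29 for SOCS3 and -2.20 for CEBPD, among 35 calls. CSF3 is at -2.59, which is uncertain, since it is listed at 0 in all whole mid-secretory libraries and a 0 here does not give the level. For lists the median differences are -1.09 for metallothioneins and 0.60 for endothelial markers by camera's preset correlation, with 0 members called in either. With an estimated correlation both are lost (camera adjusted p = 0.709 for each), and leaving out single libraries ends the calls for 7 and 2 of them.

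In 17 of 172 sets of values 1 library lies apart from the rest of its group, where normally distributed values would give 8.6 by chance. In whole proliferative endometrium these are replicate 1 with SFRP4 at 3887 FPKM (others 1563 to 2174) and MMP26 at 1175 (215 to 362), replicate 3 with PENK at 177 (16.2 to 63.2) and CBLN1 at 44.0 (13.2 to 19.6), replicate 4 with GAST at 0.14 (others 0) and a total of 401926 FPKM (463247 to 477945), and replicate 5 with TRH at 102 (22.4 to 48.0), a first component score of -51.3 (-63.7 to -59.9) and a handling list median of 3.54 (2.73 to 3.02). In whole mid-secretory endometrium replicate 4 has MMP11 at 65.4 FPKM (16.9 to 28.2) and replicate 2 BX647608 at 6.15 (9.38 to 10.5). In proliferative epithelium replicate 4 has SCGB2A2 at 14.7 (0.793 to 1.04), replicate 1 SLC47A1 at 40.8 (87.2 to 94.5) and replicate 2 TMEM185A at 0.055 (others 0). In mid-secretory epithelium replicate 2 has TRH at 1.26 (0.027 to 0.282) and MMP7 at 35.9 (6.61 to 14.4), and replicate 5 CEBPD at 173 (59.4 to 91.7). FPKM need not be normally distributed, so 8.6 is a rough guide. GAST and TMEM185A stand out only as values near 0 beside listed zeros.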

How the results depend on the processing

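The settings that leave out genes listed at 0 or the 3 lowest-weight epithelium libraries, take handling genes as a covariate, or use the second code prefix only, were chosen after the result was seen. Of 8111 alternative values of 250 named gene results, 96.1% kept their direction and side of the threshold. Fewer passed in 72 values of the whole phase comparison, 100 of the epithelium phase, 45 of phase by tissue, 8 and 10 of the tissue comparisons, and more in 35 and 27 of the phase comparisons, and 19 of the whole phase that did not pass changed sign without passing. Reversed were 4, all of mid-secretory tissue with handling genes as a covariate: IL8 -1.30, PAGE4 0.76, PLA2G2A 3.94 and SERPINF1 3.03; this covariate nearly equals the tissue difference by construction.

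The 2-fold minimum, which removes small changes, left 2068 calls in the whole phase comparison, 2402 in the epithelium phase, 942 and 1129 in proliferative and mid-secretory tissue, and 1510 shared. The first code prefix only, with fewer libraries, gave 3077 in the whole phase, 12 for phase by tissue, 1990 in mid-secretory tissue and 2154 shared. The second code prefix only, with 2 libraries per group and no proliferative epithelium, gave 783 in the whole phase and 35 in mid-secretory tissue. Handling genes as a covariate gave 2948 in the epithelium phase and 1 in each tissue comparison. Own groups only gave 3293 in the epithelium phase and 6020 in the whole phase, and array weights 4392 and 6931. Which phase comparison has more calls therefore depends on how the spread is estimated. Array weights, lower for libraries that spread more, ran from 0.252 to 1.44 in epithelium and from 0.551 to 5.01 in whole endometrium. A fit over all groups averages over such differences, and their cause was not tested. Own groups only leaves phase by tissue unchanged by construction. Phase by tissue fell to 20 with a pseudocount of 0.1 and 15 without the 3 lowest-weight libraries; the cause was not tested. Median-of-ratios scaling gave 1875 and 2713 tissue calls and quantile normalization 2328 and 2830, since both remove the -0.24 shift of all genes. With camera's estimated correlation 5 lists stay called in whole endometrium and 4 in epithelium. The replicate block gave 4488, 5079, 25, 3669 and 4396 calls in the order whole phase, epithelium phase, phase by tissue, proliferative and mid-secretory tissue.

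Leaving out 1 library at a time gave 4119 to 5080 whole phase calls, 4506 to 5239 epithelium phase calls, 3062 to 3478 shared, 2965 to 4164 and 3674 to 4883 tissue calls and 13 to 16 lists in each phase comparison. Phase by tissue ran from 17 (without epithelium proliferative replicate 3) to 74 (without epithelium proliferative replicate 2). In simulated data 28 of 100 genes changed 2-fold were found for phase by tissue against 59 to 75 in the other comparisons. These were not genes of low FPKM, and all simulated libraries had equal spread. A 2-fold difference between the phase changes is thus often missed here.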

Other observations

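No test in this part was chosen after the result was seen. Retinoid genes change in opposite directions by phase. In whole endometrium 9 rose, 6 fell and 7 did not pass (median 0.09, camera adjusted p = 0.384; 9 rose and 6 fell adjusted over the list alone), and in epithelium 7 rose, 7 fell and 8 did not pass (0.01, 0.792; 7 rose and 7 fell adjusted over the list alone). The retinol carrier RBP4 rises from 0.230 ± 0.153 to 34.5 ± 7.84 FPKM in whole endometrium (4.83, limma adjusted p = 1.51e-10) and by 5.12 in epithelium. ALDH1A3, which makes retinoic acid, rises by 4.70 and 2.86. CRABP2, which carries retinoic acid to its receptors, changes by -3.56 and -2.39, and the retinol-binding RBP7 by -3.22 and -2.97.

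Antioxidant genes also split. In whole endometrium 6 rose, 6 fell and 13 did not pass (median 0.04, camera adjusted p = 0.443; 6 rose and 6 fell adjusted over the list alone), and in epithelium 7 rose, 9 fell and 9 did not pass (median -0.13, mean 0.41 with the test pointing up, 0.951; 7 rose and 9 fell adjusted over the list alone). Beside GPX3 the mitochondrial superoxide dismutase SOD2 rises by 3.91 (limma adjusted p = 1.37e-08) in whole endometrium and 3.54 in epithelium, while GCLC, which starts glutathione synthesis, changes by -2.79 (limma adjusted p = 3.65e-07) and -2.26. Interferon response genes go both ways in whole endometrium, where 7 rose, 7 fell and 16 did not pass (0.06, 0.958; 9 rose and 9 fell adjusted over the list alone), with GBP2 at 2.80 and IFI6 at -1.66; in epithelium 6 rose, 2 fell and 22 did not pass (0.21, 0.212; 6 rose and 2 fell adjusted over the list alone), with GBP2 at 3.09. Of the unfolded protein list 4 rose, 0 fell and 17 did not pass in whole endometrium (0.08, 0.501) and 3 rose, 0 fell and 18 did not pass in epithelium (0.16, 0.431); DDIT3, a stress-induced factor, rises by 1.16 and 1.13.

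Few members of the remaining lists were tested. Of 2 B and plasma cell markers 1 rose in whole endometrium (median 0.86, camera adjusted p = 0.224) and 0 in epithelium (0.69, 0.310). Of 3 red blood cell markers 0 were called in either (-0.01 with a mean of 0.10 and the test pointing up, 0.958; -0.66, 0.640).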
